A study of Mus musculus with 9 samples.

How the data were processed

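Long-term haematopoietic stem cells (LT-HSCs) had been sorted from the bone marrow of C57BL/6 mice aged 6 to 8 weeks, per the labels, with the surface phenotype Lin-, Sca-1+, c-Kit+, CD135-, CD150+ and CD48-. Each of the 9 libraries came from 500 to 800 cells of 1 mouse: 3 wild-type (WT) mice, 3 mice lacking the chemokine gene Cxcl10 (Cxcl10-/-) and 3 lacking the chemokine receptor gene Cxcr3 (Cxcr3-/-). The replicate libraries of a group are separate mice, per the design text. Polyadenylated RNA was amplified as whole-transcriptome cDNA with the Discover-sc WTA Kit V2, and libraries were made with the TruePrep DNA Library Prep Kit V2. No day, litter or batch of preparation is given for any library.

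One deposited table holds 22322 genes, each with an Ensembl gene identifier and a symbol. Per the file headers, it gives FPKM (fragment counts normalised to transcript length and library size) for each of the 9 libraries, made by the authors. Per the file headers it also gives counts for each library, taken here to be expected counts because 87.1% of the values are whole numbers and the rest are fractions. The submitters' processing notes name fastp, HISAT2, StringTie and RSEM. Their versions, the genome build, the annotation and the denominator of the FPKM are not given in the sources used here. Of the identifiers, 22267 are in GENCODE M21; 16 genes have no symbol and 20 symbols are shared by several identifiers. The expected counts sum to between 12098498 and 17904629 per library. The reads carry no molecular identifiers, so intervals and floors derived from counts cover counting error only.

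Genes with a mean of at least 1 FPKM over the 9 libraries were tested, which left 10866. Values were analysed as log2(FPKM + 1), which understates the fold change of weakly expressed genes. A linear model with 1 mean per genotype was fitted to all 9 libraries with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and an intensity trend. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were Cxcl10-/- against WT, Cxcr3-/- against WT, Cxcr3-/- against Cxcl10-/-, the mean of both knockouts against WT, and any difference among the 3 genotypes (a moderated F test). Errors beside log2 fold changes are standard errors (SE) of the model with 3 libraries per group; errors beside FPKM are standard deviations (SD). Differences in this text are the first-named group minus the second. No replicate block was used, since nothing given ties the replicate numbers to a shared litter or day.

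The samples, comparisons, tests, gene lists, alternatives and the rule for naming genes were chosen before the data were examined, when only FPKM were assumed to be available. After the expected counts had been seen, edgeR 4.0.16 (quasi-likelihood test with TMM factors) and DESeq2 1.42.0 (Wald test) were run on the rounded expected counts of the same genes, and their results are quoted beside those of limma. Genes for which DESeq2 gave no adjusted p were kept as not called.

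Genes were named by a rule. Cxcl10, Cxcl9, Cxcl11 and Cxcr3 were always named. Per comparison of a pair of genotypes, up to 10 genes per direction with the largest change were named among those that passed, reached a mean of 5 FPKM in either group and had no overlap between the libraries of the groups, leaving out predicted genes, pseudogenes and receptor segments. Chance alone separates 3 libraries from 3 in 10% of genes. Where fewer than 5 passed, the 5 with the smallest p were named as not past the threshold. Up to 4 members of each list that passed, and up to 2 of each list of stem cell identity, self-renewal, quiescence, cell cycle, interferon and lineage priming, were named by their p. Any list member that passed over all genes was open to naming. A gene picked by the rule is not reported, and no other took its place. A gene named outside this rule is said to have been chosen after its values were seen.

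The 41 gene lists covered long-term HSC identity, self-renewal regulators, quiescence regulators, S phase, G2 and mitosis, interferon response, MHC class I and class II presentation, the CXCR3 axis, chemokines and chemokine receptors, NF-kB and inflammatory response, immediate-early and dissociation stress, TGF-beta and BMP signalling, and adhesion and homing. They further covered myeloid, lymphoid and megakaryocyte priming, erythroid cells, neutrophils, monocytes and macrophages, B cells, T and NK cells, dendritic cells, mast cells with basophils and eosinophils, endothelial cells, and stromal and bone cells. The others were p53 targets, apoptosis regulators, unfolded protein response, antioxidant response, autophagy, glycolysis, cholesterol synthesis, ribosome biogenesis, cytoplasmic ribosomal proteins, nuclear and mitochondrial genes of oxidative phosphorylation, replication-dependent histones, the genomic neighbours of Cxcl10 and of Cxcr3, and sex-linked genes. The 37 lists with at least 5 measured members were tested with limma's camera, two-sided, with a preset inter-gene correlation of 0.01, which compares the members with all other tested genes. Adjustment was over the lists of a comparison. Camera with an estimated correlation and fry, a rotation test, were run beside it. The main p of fry tests whether the genes of a list move, on balance, one way, its mixed p tests whether they change in either direction, and neither compares the list with other genes.

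Single values were compared with exact two-sided permutation tests, whose smallest p for 3 against 3 libraries is 0.1. A fold change against a group with 0 counts in all its libraries is given as a bound, computed against 3 counts over the whole group. Because both knockouts were compared with the same 3 WT libraries, the correlation of their changes was set beside 100 simulations of unchanged groups.

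The alternatives chosen before the data were examined were a pseudocount of 0.1 or 0.5, no filter on low values or a mean of at least 5 FPKM, rescaling to the same sum, median-of-ratios scaling, quantile normalization, no intensity trend, robust moderation, array weights, a replicate block, only the 6 samples compared, a 2-fold minimum, leaving out each library in turn, an estimated correlation and fry. Those added after seeing the data were edgeR, DESeq2 with and without independent filtering, leaving out the mitochondrial genes and rescaling, a loess correction for GC content and transcript length, the genes above 0 in all libraries, edgeR on the 6 samples of Cxcr3-/- and WT, and leaving out the endothelial, stromal, erythroid and immediate-early lists. GC content and length were those of the longest GENCODE M21 transcript of each gene and were found for 99.9% of the tested genes.

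The tests were also tested on simulated data with 200 changed genes in each of 5 simulations, built from the means of these libraries and the spread of each genotype. After a first simulation had been seen, the other 4 and a version with 1 spread for the 3 genotypes were added; the report gives the outcome beside the counts it bears on. All 9 libraries and every column of the table were used.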

Results

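The transcriptome of LT-HSCs was measured in 9 mice: 3 WT, 3 Cxcl10-/- and 3 Cxcr3-/-. CXCR3 is the receptor of the interferon-induced chemokines CXCL9, CXCL10 and CXCL11, and the series concerns the part of Cxcl10 and Cxcr3 in the self-renewal and differentiation of these stem cells. The expected counts summed to 14368247, 15252788 and 17904629 in the WT libraries, 13550279, 14128999 and 15852241 in the Cxcl10-/- libraries and 12805633, 15868608 and 12098498 in the Cxcr3-/- libraries. Of the 22322 genes, 15123 ± 796 (SD, n = 3) were above 0 in WT, 13225 ± 675 in Cxcl10-/- and 16856 ± 1974 in Cxcr3-/-. Of the 10866 tested genes, 65 were at 0 in an average WT library, 260 in a Cxcl10-/- library and 70.3 in a Cxcr3-/- library. Transcripts of the mitochondrial genome took 12.9 ± 0.258% (SD, n = 3) of the counts in WT, 3.89 ± 0.287% in Cxcl10-/- and 10.8 ± 0.479% in Cxcr3-/-. The 10 most abundant genes of a library took 13.8% of its counts in WT, 6.32% in Cxcl10-/- and 11.7% in Cxcr3-/-.

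The Cxcl10-/- libraries stood apart from the others and from each other. Across genes, the median Pearson r of log2(FPKM + 1) between replicates was 0.968 in WT, 0.954 in Cxcr3-/- and 0.886 in Cxcl10-/-. Between groups it was 0.949 for Cxcr3-/- and WT, 0.895 for Cxcl10-/- and WT, and 0.881 for Cxcl10-/- and Cxcr3-/-. Genes are not independent replicates, so these values describe the libraries and test nothing. Principal component 1 held 34.4% of the variance and parted the Cxcl10-/- libraries from the other 6, while component 2, with 19.8%, mainly parted the Cxcl10-/- libraries from one another.

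**Figure D1:**
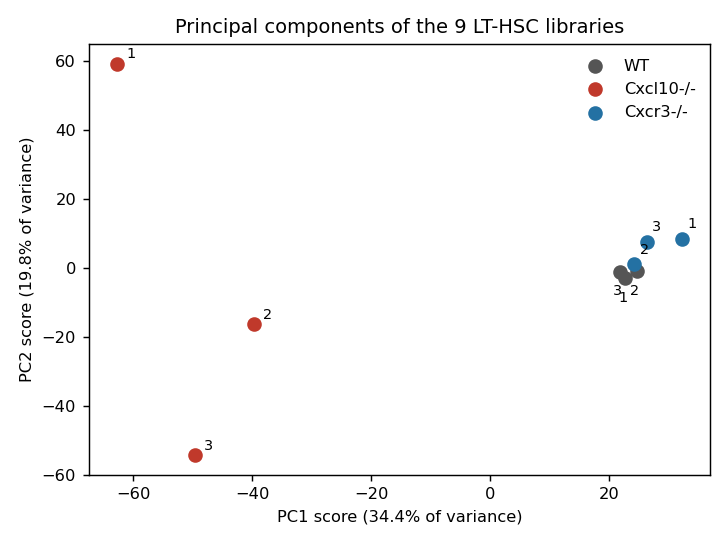
Principal component scores of the 9 libraries from log2(FPKM + 1) of the 10866 tested genes, with component 1 (34.4% of the variance) on the horizontal axis and component 2 (19.8%) on the vertical axis; each point is a library labelled by its replicate. The 3 Cxcl10-/- libraries lie apart from the other 6 and are spread over component 2.

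The deleted genes themselves were looked at first, because they test the labels. Cxcl10 (ENSMUSG00000034855) had 0 counts in each Cxcl10-/- library, 36, 84 and 3 counts in WT, and 112, 553 and 176 counts in Cxcr3-/-. This was at least 37.6-fold below WT and at least 299-fold below Cxcr3-/- (exact permutation p = 0.1 against WT, the smallest that 3 against 3 libraries allow). Against WT the adjusted p of Cxcl10 was 0.142 in limma and 0.0233 in edgeR. In Cxcr3-/- cells, Cxcl10 stood at 17.7 ± 12.6 FPKM (SD, n = 3) against 2.49 ± 2.45 in WT, with no overlap between the libraries (exact permutation p = 0.1). In limma this difference of 2.51 ± 0.61 (log2, SE) had an adjusted p of 0.441. Cxcr3 (ENSMUSG00000050232) had 0, 0 and 8 counts in WT and 0 in every knockout library, so the Cxcr3-/- labels could not be checked from its level. Cxcl11 (ENSMUSG00000060183) had at most 5 counts in any library. Cxcl9 (ENSMUSG00000029417) stood at 4.33 ± 0.636 FPKM in Cxcl10-/- against 0.32 ± 0.392 in WT, a rise of 2.05 ± 0.44 (adjusted p = 0.0158). That call ended without WT replicate 1 (1.96, adjusted p = 0.0712) or WT replicate 2 (1.90, 0.0806), though the size of the rise hardly moved, and edgeR gave 0.0736. Cxcl9 is also a genomic neighbour of Cxcl10; the 12 measured neighbours had a median of -0.20 and a mean of 0.00 (adjusted p = 0.592), with only Cxcl9 past the threshold.

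Cxcl10-/- against WT asks what loss of the ligand changes in LT-HSCs. Fos, an immediate-early transcription factor gene, rose from 0.99 ± 0.771 to 121 ± 50.2 FPKM (log2 5.93 ± 0.45, SE, n = 3 per group). Fabp4, a fatty acid carrier of capillary endothelium, rose from 9.94 ± 7.17 to 361 ± 85.6 FPKM (5.21 ± 0.63). Of the 32 genes of G2 and mitosis 14 were called lower, among them the spindle gene Nusap1 (-4.31 ± 0.42) and Ccnb1, which encodes cyclin B1 (-3.26 ± 0.51); the list did not pass with an estimated correlation (adjusted p = 0.108). Of the 13 protein-coding transcripts of the mitochondrial genome 12 fell, led by mt-Atp8 (-3.39 ± 0.24) and, among the most abundant, mt-Atp6, which dropped from 52397 to 9352 FPKM (-2.49 ± 0.10). The lists of cytoplasmic ribosomal proteins and of nuclear genes of oxidative phosphorylation had medians of 0.33 and 0.30, with 36 of 83 and 22 of 81 genes called higher. Neither list passed with an estimated correlation (adjusted p = 0.454 each), and the nuclear median was 0.08 after quantile normalization. The ribosomal median went as low as 0.10 over the alternatives.

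In limma, 1008 of the 10866 genes passed in Cxcl10-/- against WT, 663 higher and 345 lower, and 648 of them differed at least 2-fold. At an unadjusted p under 0.05 there were 2825 genes, where 543.3 would arise by chance. Across the 10856 genes with a GC value, the log2 fold change rose with GC content (rho 0.397). That rho was 0.197 in Cxcr3-/- against WT and -0.263 in Cxcr3-/- against Cxcl10-/-, and its cause was not tested. After GC and length correction 609 genes were called, with 469 of the 1008 among them in the same direction. edgeR called 785 (383 higher, 402 lower) and DESeq2 1498 (718 higher, 780 lower); 625 were called by limma and edgeR in the same direction. The share of higher genes depended on the scaling: it was 402 of 808 after median-of-ratios scaling, 433 of 923 after quantile normalization and 334 of 900 with the mitochondrial genes left out, which moved the median of all genes by -0.20 (log2). In simulated data with the spread of each genotype kept, limma recovered 13.4%, 53.7% and 75.8% of genes changed 2-, 4- and 8-fold, but 155 of its 630 calls (24.6%) were unchanged genes; for edgeR that share was 15.7%. With 1 spread for the 3 genotypes, a version added after the first result was seen, the shares were 4.11% and 3.45%. The calls were summed over 5 simulations with 200 changed genes each. Such a share depends on how many genes change, so it does not give the share of unchanged genes among the 1008. The count was 362, 282 and 413 without WT replicates 1, 2 and 3, and lay between 817 and 1192 without any one of the other libraries.

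Besides Fos and Fabp4, the genes with the largest rises were Rarres2, which encodes the chemoattractant chemerin (5.13 ± 0.58), Sparc, a matrix glycoprotein gene (4.90 ± 0.45), and Stab1, a scavenger receptor gene of sinusoidal endothelium (4.88 ± 0.41). They were followed by Ubd, an interferon-inducible ubiquitin-like gene (4.84 ± 0.76), Ibsp, which encodes bone sialoprotein (4.78 ± 0.53), and Ackr1, a decoy chemokine receptor gene of venules (4.58 ± 0.55). Depp1, a FOXO-responsive gene (4.53 ± 0.56), and Gpihbp1, which anchors lipoprotein lipase on capillaries (4.43 ± 0.81), completed the 10. Their adjusted p lay between 2.74e-05 for Fos and 0.00738 for Gpihbp1. edgeR did not call Gpihbp1 (adjusted p = 0.0717).

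Among the genes with the largest falls, the histone gene H2ac4 had 0 counts in Cxcl10-/- and was at least 109-fold lower than in WT. Nusap1, Ccnb1, Pimreg, a mitotic regulator gene (-3.35 ± 0.44), Knl1, which encodes a kinetochore scaffold (-3.26 ± 0.45), and Cdca3, a trigger of mitotic entry (-3.03 ± 0.70), belong to cell division. Nxt2, an mRNA export factor gene (-3.21 ± 0.46), Zfp54, a zinc finger gene (-3.16 ± 0.48), and Fhit, a tumour suppressor gene at a fragile site (-2.89 ± 0.54), fell as well. Adjusted p ran from 1.29e-05 for mt-Atp8 to 0.0208 for Cdca3. Cdca3 did not pass without WT replicates 1, 2 or 3 (0.0710, 0.0761 and 0.0727), and edgeR called neither Cdca3 (adjusted p = 0.188) nor Fhit (0.0946).

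**Figure D2:**
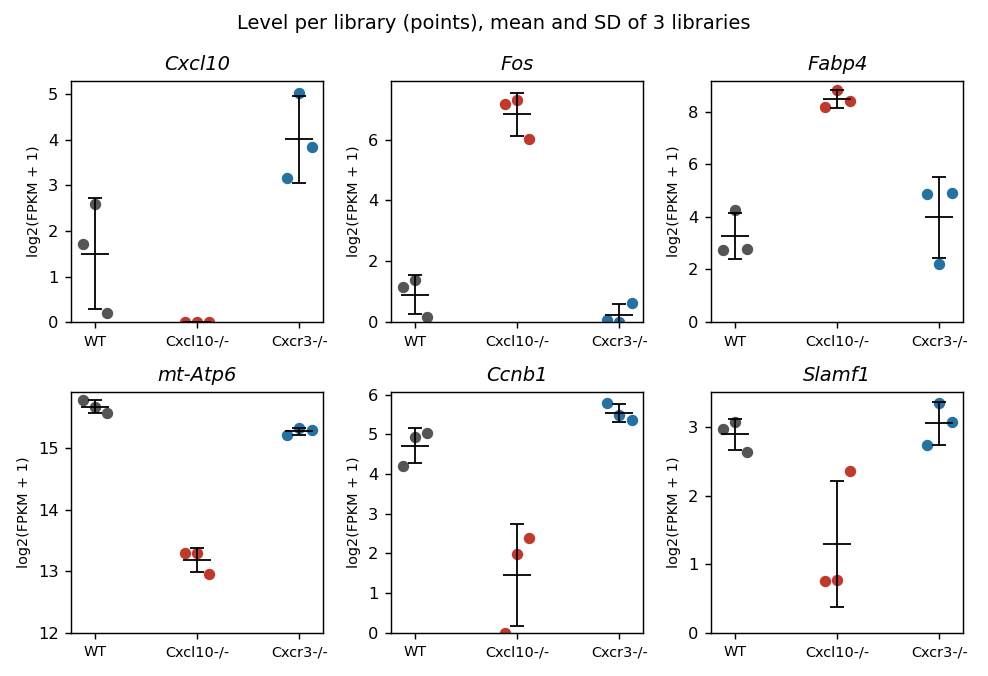
Log2(FPKM + 1) of 6 genes in each of the 9 libraries, grouped by genotype on the horizontal axis; points are libraries, bars are the mean and SD of 3, and the axis of mt-Atp6 starts at 12. Fos and Fabp4 are higher and mt-Atp6 and Ccnb1 lower in each Cxcl10-/- library than in each WT library, and Cxcl10 is at 0 in the Cxcl10-/- libraries.

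Of the 37 lists tested in Cxcl10-/- against WT, camera with the preset correlation passed 14, 9 higher and 5 lower. None of the 14 held with an estimated correlation. With its directional p fry passed 16: 12 of the 14, without MHC class II (adjusted p = 0.182) and histones (0.0646), and 4 lists that camera did not pass. With its mixed p fry passed 35 of the 37, all but interferon response and neutrophils, so that p parts few lists from the others here. The mitochondrial genes of oxidative phosphorylation had the smallest p: their median was -1.47 (adjusted p = 7.45e-25; 0.0742 with an estimated correlation), with 12 of 13 lower over all genes and 12 adjusted over the list alone. mt-Cytb fell by 2.37 (SE 0.11), mt-Co3 by 1.47 (SE 0.08) and mt-Co1 by 1.34 (SE 0.07), whereas mt-Nd3 was not called (-0.01 ± 0.14). The nuclear genes of the same process had a median of 0.30 (adjusted p = 3.3e-06; 0.454 with an estimated correlation), with 22 of 81 higher and none lower, or 33 higher and 1 lower adjusted over the list alone. Among them were the complex I genes Ndufb7 (1.02 ± 0.12), Ndufs6 (0.89 ± 0.14) and Ndufb10 (1.12 ± 0.17) and the ATP synthase gene Atp5h (0.85 ± 0.13). After quantile normalization their median was 0.08 and the list did not pass (adjusted p = 0.277).

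Among the cell cycle lists, that of G2 and mitosis had a median of -1.33 (adjusted p = 1.93e-14; 0.108 with an estimated correlation), with 14 of 32 genes lower and none higher, or 21 lower adjusted over the list alone. The cytokinesis gene Anln (-2.69 ± 0.41) and the cyclin B2 gene Ccnb2 (-1.85 ± 0.32) were among them. The 34 S phase genes had a median of -0.19 and did not pass (adjusted p = 0.352), with 1 higher and 2 lower, or 1 and 3 adjusted over the list alone. The DNA repair gene Ung rose (1.85 ± 0.38), while Slbp, which binds histone mRNA, fell (-0.75 ± 0.16). Both calls ended with a WT library left out, though the size of the changes hardly moved. Without WT replicate 1 Ung stood at 1.86 (adjusted p = 0.0512) and Slbp at -0.74 (0.0671). Without WT replicate 2 they stood at 1.73 (0.0651) and -0.69 (0.0859). The E2F family gene E2f8 fell by 1.46. Replication-dependent histones had a median of -0.71, also with genes at 0 counts set at their bound (adjusted p = 0.000292; 0.427 with an estimated correlation). Of 32 measured, 6 were lower and 1 higher, or 8 and 2 adjusted over the list alone. H4c4 (-2.82 ± 0.42) and H2ac8 (-2.24 ± 0.42) fell, H2bc18 was at least 19.8-fold lower, and H2ac18 rose by 1.41. H2bc18 did not pass without WT replicate 1 (adjusted p = 0.0601). Among genes above 0 in all libraries the histone median was -0.15 and the list did not pass (0.0798); it was -0.42 without Cxcl10-/- replicate 1 and -1.14 without Cxcl10-/- replicate 2.

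The immediate-early and endothelial lists moved the other way, and so did part of the stromal list. The immediate-early and dissociation stress list had a median of 2.44 (adjusted p = 4.04e-13; 0.0742 with an estimated correlation), with 12 of 16 higher and none lower, or 15 higher adjusted over the list alone. Egr1 (4.28 ± 0.49), Jun (2.73 ± 0.38) and Ier2 (2.58 ± 0.29), which serum or tissue handling can induce, were among them. Endothelial genes had a median of 1.87 (adjusted p = 3.23e-07; 0.0742 with an estimated correlation), with 9 of 12 higher, or 10 adjusted over the list alone. The tight junction gene Cldn5 (3.42 ± 0.42), the hyaluronan receptor gene Stab2 (2.52 ± 0.38) and the fenestral diaphragm gene Plvap (1.94 ± 0.39) rose with Fabp4. Plvap did not pass without WT replicate 1 (adjusted p = 0.0547) or WT replicate 2 (0.0586). Cdh5, Flt4, Plvap and Stab2 reached the mean of 1 FPKM over the 9 libraries only through the Cxcl10-/- libraries. The positive endothelial median is therefore partly fixed by the filter. Fos and Fosb of the immediate-early list reached it in the same way. Cdh5, Flt4 and Fosb were chosen after their values were seen. Stromal and bone genes had a median of 1.94, or 4.35 with Adipoq at its bound (adjusted p = 0.0357; 0.454 with an estimated correlation), with 2 of 5 higher over all genes and over the list alone. Cxcl12, the chemokine of the stem cell niche, stood at 14.1, 119 and 10.8 FPKM in the 3 Cxcl10-/- libraries (4.35 ± 0.73). The adipokine gene Adipoq stood at 1.37, 21.8 and 0.05 FPKM there and had no counts in WT (at least 154-fold higher). In limma Adipoq had an adjusted p of 0.176, and 0.0363 without Cxcl10-/- replicate 3. The leptin receptor gene Lepr did not pass (0.86 ± 0.66). Adipoq, Cxcl12 and Lepr reached the mean of 1 FPKM over the 9 libraries only through the Cxcl10-/- libraries. Members near 0 in every group, such as Col1a1, were left out, so the positive median is partly fixed by the filter. Runx2 stood lower in Cxcl10-/- (10.7, 10.4 and 8.05 FPKM) than in WT (13.4, 15.9 and 14.5). Col1a1 and Runx2 were chosen after their values were seen. Without Cxcl10-/- replicate 2 the stromal list had a median of 0.66 and did not pass (adjusted p = 0.132), nor did it with a pseudocount of 0.1 (0.071) or without the intensity trend (0.0515).

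Lists of protein synthesis passed with positive medians. Cytoplasmic ribosomal protein genes had a median of 0.33 (adjusted p = 7.24e-11; 0.454 with an estimated correlation), with 36 of 83 higher and 1 lower, or 44 and 2 adjusted over the list alone. Rpl8 (1.12 ± 0.13), Rps15 (0.89 ± 0.12), Rpl19 (0.80 ± 0.10) and Rps6 (0.77 ± 0.10), structural proteins of the ribosome, were among them. Over the alternatives the median of this list ranged from 0.10 to 0.44. Leaving out the mitochondrial genes and rescaling moved the median of all genes by -0.20, so part of the 0.33 and of these calls can follow from the scaling. Ribosome biogenesis genes had a median of 0.36 (adjusted p = 6.23e-05; 0.0742 with an estimated correlation), with 6 of 28 higher, or 11 adjusted over the list alone. The nucleolar genes Ppan (1.90 ± 0.28) and Nolc1 (1.28 ± 0.24) rose. Nop16 (1.31 ± 0.26) and Ebna1bp2 (1.35 ± 0.29) rose too, but not without WT replicate 2 (adjusted p = 0.058 and 0.0709) or WT replicate 3 (0.0525 and 0.0602). The unfolded protein response had a median of 0.54 (adjusted p = 0.0215; 0.441 with an estimated correlation), with 6 of 22 higher and 1 lower, or 7 and 1 adjusted over the list alone. The chaperone gene Hsp90b1 (1.00 ± 0.15) and the phosphatase subunit gene Ppp1r15a (1.95 ± 0.35) rose and the co-chaperone gene Dnajb9 fell (-1.01). The calreticulin gene Calr rose by 0.88, though not without WT replicate 3 (adjusted p = 0.0601). This list did not pass without Cxcl10-/- replicate 1 (0.111), without WT replicate 3 (0.0961) or after quantile normalization (0.0749), and its median was 0.82 without Cxcl10-/- replicate 3.

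Metabolic and antigen presentation lists passed in both directions. Cholesterol synthesis genes had a median of -0.46 (adjusted p = 0.000415; 0.112 with an estimated correlation), with 5 of 24 lower, or 8 lower and 1 higher adjusted over the list alone. The isomerase gene Idi1 (-2.33 ± 0.29) and the sterol oxidase gene Msmo1 (-1.81 ± 0.26) fell. Sqle (-1.45 ± 0.28) and Nsdhl (-2.05 ± 0.41) fell as well, but not without WT replicate 1 (adjusted p = 0.0564 and 0.054) or WT replicate 2 (0.0501 and 0.0502). Glycolysis genes had a median of 0.31 (adjusted p = 0.00929; 0.238 with an estimated correlation), with 3 of 18 higher over all genes and over the list alone, Gpi1 (1.09 ± 0.19) among them. The glycolysis list did not pass after quantile normalization (0.0835) or after correction for GC content and length (0.364). MHC class I genes had a median of 0.56 (adjusted p = 0.0105; 0.454 with an estimated correlation), with 6 of 14 higher and 1 lower, or 8 and 1 adjusted over the list alone. The class I heavy chain gene H2-K1 rose (0.55 ± 0.10) while B2m, the light chain gene, fell (-1.11 ± 0.14). The immunoproteasome gene Psmb10 rose by 1.01, though not without WT replicate 2 (adjusted p = 0.0569). The class I list did not pass after quantile normalization (0.0835) or GC and length correction (0.315). MHC class II genes had a median of -0.55 (adjusted p = 0.0242; 0.454 with an estimated correlation), with none of the 10 past the threshold over all genes or over the list alone. H2-Eb1 (-1.40 ± 0.51) and H2-Aa (-0.78 ± 0.37) stood lowest in p with H2-DMb2 and H2-Ob. The class II list did not pass without Cxcl10-/- replicate 3 (0.0636) or WT replicate 3 (0.0961), in edgeR (0.0573) or with a mean of at least 5 FPKM (0.0577).

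Lists of stem cell function did not pass camera in Cxcl10-/- against WT. Long-term HSC identity had a median of 0.12 (adjusted p = 0.84; 31 genes, 1 higher and 1 lower). Tgm2, a transglutaminase gene, rose (1.06 ± 0.28, adjusted p = 0.034), though not without Cxcl10-/- replicate 3 (0.0705), Cxcr3-/- replicate 2 (0.0507), Cxcr3-/- replicate 3 (0.0505) or WT replicates 1, 2 and 3 (0.125, 0.124 and 0.0696). Slamf1, which encodes the sort marker CD150, stood at 0.69, 0.71 and 4.12 FPKM in the Cxcl10-/- libraries against 6.87, 7.4 and 5.23 in WT (-1.60 ± 0.45, adjusted p = 0.0458; edgeR 0.119). That call ended without any one library other than Cxcl10-/- replicate 3, with adjusted p from 0.0616 to 0.158. Self-renewal regulators had a median of 0.14 (adjusted p = 0.84; 3 of 36 higher), with Hoxa10 at 1.17 ± 0.31 and Stat3 at 0.80 ± 0.23. Hoxa10 did not pass without Cxcl10-/- replicate 3, Cxcr3-/- replicates 1 or 3, or any WT library (0.0523 to 0.144). Stat3 did not pass without any one library except Cxcl10-/- replicate 2 (0.0577 to 0.156). Quiescence regulators had a median of 0.37 (adjusted p = 0.14 in camera and 0.0273, higher, in fry), with 6 of 24 higher and 3 lower, or 8 and 5 adjusted over the list alone. Nr4a1 (3.74 ± 0.57), Klf2 (3.33 ± 0.58) and Btg2 (3.13 ± 0.62) rose, and the retinoblastoma family genes Rbl1 (-1.49 ± 0.28) and Rbl2 (-1.35 ± 0.31) fell with the cell cycle inhibitor gene Cdkn2c (-2.60 ± 0.59). Egr1, Nr4a1 and Btg2, 3 of the 6 called higher, are also in the immediate-early list.

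Signalling and lineage lists did not pass camera either, but 3 of them passed the directional p of fry, all higher: NF-kB and inflammatory response (adjusted p = 0.00593), the CXCR3 axis (0.0199) and myeloid priming (0.00406). The medians were 0.22 for interferon response (37 genes, 0 past the threshold by limma; adjusted p = 0.84), 0.04 for the CXCR3 axis (5 genes, 2 higher and 1 lower; 0.84) and 0.20 for chemokines and chemokine receptors (12 genes, 1 higher and 1 lower; 0.934). In the CXCR3 axis, Dpp4, a protease that inactivates CXCL10, fell by 2.02; in the chemokine list, Cxcl12 was the gene called higher, and Ccl6, at least 37.2-fold lower in Cxcl10-/-, the gene called lower. Irf1 (0.75 ± 0.23, adjusted p = 0.0576) and Cmpk2 (-1.20 ± 0.36, 0.061) led the interferon list without passing; Cmpk2 passed without Cxcl10-/- replicate 3 (0.0195). The medians were 0.29 for NF-kB and inflammatory response (adjusted p = 0.226) and -0.23 for adhesion and homing (0.168). For TGF-beta and BMP signalling the median was -0.05 and the mean 0.13, with a lower direction in camera (0.84); the BMP target gene Id3 rose (3.32 ± 0.62). Myeloid priming had a median of 0.52 (adjusted p = 0.0955), with Cebpb higher (2.01 ± 0.36; edgeR 0.0527), and lymphoid priming 0.25 (0.666), with Lsp1 higher (1.06 ± 0.24), though not without WT replicate 1 (0.0843) or WT replicate 2 (0.0968). Megakaryocyte priming had a median of 0.01, a mean of -0.15 and a lower direction in camera (0.401); the platelet signalling genes Plek (-1.72 ± 0.32) and Rap1b (-0.92 ± 0.15) fell.

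The remaining lists bear on other cells and on stress in Cxcl10-/- against WT, and none of those tested passed camera or fry with its directional p; with the mixed p of fry all but neutrophils (adjusted p = 0.136) passed. The medians were 0.22 for erythroid cells (adjusted p = 0.9), 0.83 for neutrophils (0.84), 0.14 for monocytes and macrophages (0.507) and -0.47 for T and NK cells (0.507). The haemoglobin gene Hba-a1 (2.77 ± 0.56), the adhesion gene Vcam1 (3.26 ± 0.48) and the mannose receptor gene Mrc1 (1.97 ± 0.44) rose. Other members lay lower in each Cxcl10-/- library than in each WT library. Car2 of the erythroid list stood at 480, 510 and 398 FPKM against 1086, 850 and 849. Anxa1 of the neutrophil list stood at 139, 149 and 141 against 251, 211 and 214. Car2 and Anxa1 were chosen after their values were seen. The medians were 0.45 for p53 targets (0.84), 0.18 for apoptosis regulators (0.59) and 0.07 for autophagy (0.934). The antioxidant list had a median of 0.15, a mean of -0.08 and a lower direction in camera (0.84), with the quinone reductase gene Nqo1 lower (-2.0 ± 0.40). The neighbours of Cxcr3 had a median of 0.05, a mean of -0.06 and a lower direction (0.955). B cell genes (3 measured, median 1.14), dendritic cell genes (3, 0.27), genes of mast cells, basophils and eosinophils (2, -0.64) and sex-linked genes (4, -0.18) were too few to test.

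Cxcr3-/- against WT asks what loss of the receptor changes, and no gene passed in limma. The genes with the smallest p, none past the threshold, were Rgs18, a regulator of G protein signalling in platelets (-0.84 ± 0.15, SE, adjusted p = 0.353), and Prr13, a proline-rich protein gene (-1.11 ± 0.19, 0.353). They were followed by mt-Cytb, which encodes mitochondrial cytochrome b (-0.58 ± 0.11, 0.427), the lysozyme gene Lyz2 (-0.97 ± 0.20, 0.441) and Il2rg, the common gamma chain gene, which lies near Cxcr3 (-1.05 ± 0.22, 0.441). On the higher side stood Xlr3a, an X-linked lymphocyte-regulated gene (2.62 ± 0.50, 0.427), mt-Nd3 (0.73 ± 0.14, 0.438), H2-K1 (0.47 ± 0.10, 0.441), the actin gene Actb (0.54 ± 0.11) and Mat2a, which makes S-adenosylmethionine (0.67 ± 0.14).

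For Cxcr3-/- against WT, limma called 0 of 10866 genes, with 834 at an unadjusted p under 0.05 against 543.3 by chance, and edgeR called 0 with 681. DESeq2 called 78 (17 higher, 61 lower) and gave no adjusted p to 8637 genes; without independent filtering it called 30 (4 higher, 26 lower). limma called 0 in the 6 samples alone as well, and 1 gene, the predicted gene Gm4724, without WT replicate 2. With array weights limma called 4, all lower: Rgs18, Prr13, mt-Cytb and 1110032A03Rik; Gm4724 and 1110032A03Rik lie outside the naming rule and were chosen after their values were seen. In simulated data with the spread of each genotype kept, limma on 9 libraries recovered 6.87%, 47.5% and 74.8% of genes changed 2-, 4- and 8-fold, with 0.464% unchanged genes among its calls, so 2-fold changes were mostly not detectable. With 1 spread for the 3 genotypes it recovered 11.3%, 46.9% and 74.5%, with 6.55% unchanged genes. On the 6 libraries, with the spread of each genotype kept, it recovered 20%, 67.8% and 86.4%.

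Of the 37 lists, 5 passed camera with the preset correlation in Cxcr3-/- against WT; none of them passed with an estimated correlation or with the directional p of fry. With the mixed p of fry 4 lists passed: MHC class I (adjusted p = 0.0101), mitochondrial oxidative phosphorylation (0.0153), S phase (0.022) and ribosome biogenesis (0.0461). The number that passed camera with the preset correlation was 3 without Cxcl10-/- replicate 3 or WT replicate 1, and 8 without Cxcr3-/- replicate 1. Cytoplasmic ribosomal protein genes had a median of 0.29 (adjusted p = 9.88e-26; 0.515 with an estimated correlation), with 0 of 83 past the threshold over all genes and 34 higher and 1 lower adjusted over the list alone. Rpl39 (0.65 ± 0.14), Rplp2 (0.79 ± 0.18) and Rps14 (0.41 ± 0.10) were among the genes with the smallest p in the list. MHC class I genes had a median of 0.39 (adjusted p = 3e-05; 0.515 with an estimated correlation), with 5 of 14 higher adjusted over the list alone. H2-Q7 (0.66 ± 0.16), the peptide-loading gene Tapbp (0.74 ± 0.21) and Psmb9 (0.53 ± 0.17) followed H2-K1. Self-renewal regulators had a median of 0.23 (adjusted p = 0.0279; 0.685 with an estimated correlation), with Hoxa10 at 0.91 ± 0.31 and the Polycomb methyltransferase gene Ezh2 at 0.71 ± 0.27. This list did not pass without Cxcr3-/- replicate 1 (adjusted p = 0.0766), without WT replicate 1 (0.0757), without the filter on low values (0.223) or after GC and length correction (0.151).

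The other lists that passed in Cxcr3-/- were small in size of change. The mitochondrial genes of oxidative phosphorylation had a median of -0.08 (adjusted p = 0.0279; 0.685 with an estimated correlation), with 2 of 13 higher and 4 lower adjusted over the list alone, and the direction flipped to a median of 0.17 after GC and length correction (adjusted p = 0.151). mt-Atp6 stood at -0.40 ± 0.10, mt-Co1 at -0.30 ± 0.07 and mt-Atp8 at -0.83 ± 0.24. The mitochondrial list did not pass without Cxcl10-/- replicate 3 (0.0521), Cxcr3-/- replicate 2 (0.0514), Cxcr3-/- replicate 3 (0.168, median -0.03) or WT replicate 2 (0.0674), after quantile normalization (0.55) or without the intensity trend (0.193); its median was -0.12 without Cxcr3-/- replicate 1. The antioxidant list had a median of -0.10 (adjusted p = 0.0309; 0.685 with an estimated correlation), with the ferritin genes Fth1 (-0.53 ± 0.15) and Ftl1 (-0.80 ± 0.24), Mgst1 (-1.02 ± 0.30) and the haem oxygenase gene Hmox1 (-1.30 ± 0.45) lowest in p. It did not pass without Cxcl10-/- replicate 3 (0.0635), Cxcr3-/- replicate 1 (0.228, median -0.04), WT replicate 1 (0.067, median -0.07) or WT replicate 3 (0.088, median -0.02), with a mean of at least 5 FPKM (0.133), without the trend (0.103), with array weights (0.0746) or after GC and length correction (0.0635).

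Apart from self-renewal regulators, the lists of stem cell function, cell cycle and lineage did not pass in Cxcr3-/- against WT. Long-term HSC identity had a median of -0.02 (adjusted p = 0.333), with Gata2 at 0.69 ± 0.24 and Sult1a1 at -1.06 ± 0.43, and quiescence regulators had one of 0.24 (0.271), with the inhibitor gene Cdkn1b at 0.83 ± 0.36. S phase had a median of 0.05 (adjusted p = 0.251; Mcm5 0.76 ± 0.22) and passed without Cxcr3-/- replicate 3 (0.0142). G2 and mitosis had a median of 0.20 (0.203; Plk1 1.40 ± 0.53). The interferon list had a median of -0.07 and a mean of 0.00 (0.794), with Irf1 at 0.84 ± 0.23 and the GTPase gene Irgm2 at 1.23 ± 0.36. The CXCR3 axis had a median of 0.61 (adjusted p = 0.0962) and 2 of 5 genes higher adjusted over the list alone, and it passed without Cxcr3-/- replicate 1 (0.0257). Without that library MHC class II (0.173; 0.000761), nuclear oxidative phosphorylation (0.392; 3.39e-05) and histones (0.166; 0.00233) passed as well, and so did glycolysis (0.0512), with 0.0141 there and 0.0343 without WT replicate 3. The immediate-early list had a median of -0.13 (0.529) and the endothelial list 0.17 (0.735). Among priming lists, the platelet factor gene Pf4 (0.77 ± 0.19), the transcription factor genes Tcf3 (1.03 ± 0.34) and Spi1 (-0.72 ± 0.31) led without passing.

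**Figure D3:**
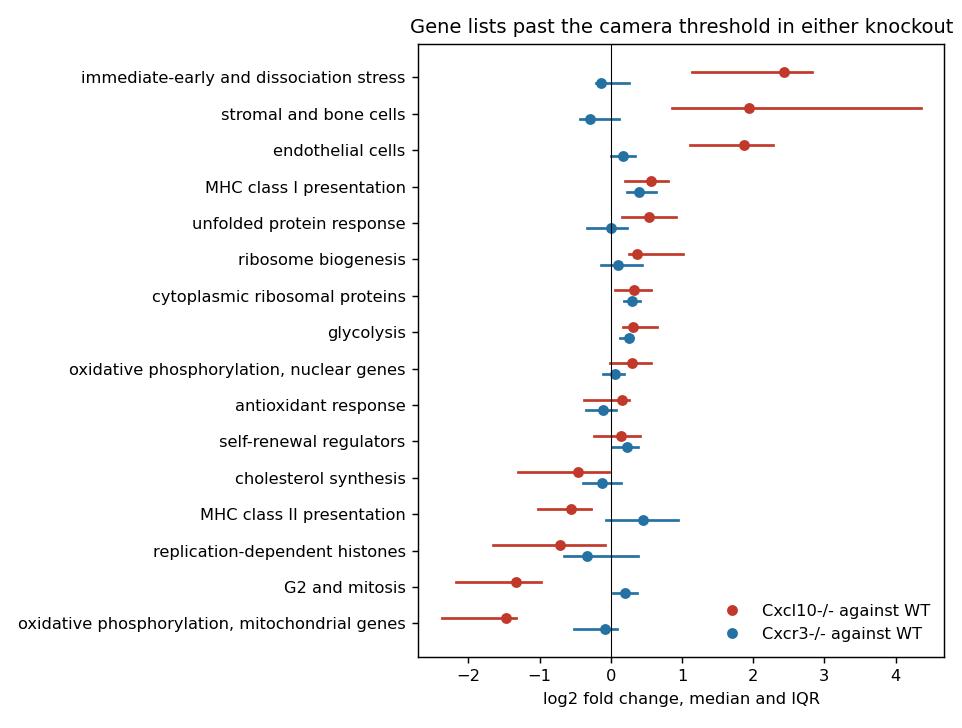
Median and interquartile range of the log2 fold change against WT for 16 gene lists, shown for Cxcl10-/- and for Cxcr3-/-, with the lists on the vertical axis. The immediate-early list (2.44 and -0.13) and the mitochondrial list (-1.47 and -0.08) part the knockouts, and the mitochondrial median of Cxcr3-/- flips to 0.17 after GC and length correction.

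Cxcr3-/- against Cxcl10-/- tests whether the knockouts differ; the WT libraries drop out of the difference but not out of the spread it is judged by. Of the 32 genes of G2 and mitosis 19 were called higher in Cxcr3-/-, though the list did not pass with an estimated correlation (adjusted p = 0.114): Nusap1 by 4.29 ± 0.42 (log2, SE, n = 3 per group), Ccnb1 by 4.08 ± 0.51, Pimreg by 3.90 ± 0.44 and the kinase gene Aurkb by 3.02 ± 0.50. Cxcl10 itself was at least 299-fold higher, and the histone genes H2ac4 and H2bc18 were at least 139-fold and 50.9-fold higher. Fos (-6.60 ± 0.45), Stab1 (-5.34 ± 0.41), Sparc (-5.33 ± 0.45) and Ibsp (-4.96 ± 0.53) were lower in Cxcr3-/-.

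In limma, 1359 genes passed between the knockouts, 510 higher and 849 lower in Cxcr3-/-, 938 of them at least 2-fold. There were 3026 at an unadjusted p under 0.05. edgeR called 1142 (554 higher, 588 lower), with 936 shared with limma in the same direction, and DESeq2 1814 (859 higher, 955 lower). The split was 717 higher and 612 lower after quantile normalization, and 794 and 525 with the mitochondrial genes left out, which moved the median of all genes by 0.16. Without Cxcr3-/- replicate 1 the count was 596 and without Cxcr3-/- replicate 3 it was 754; without any one of the other libraries it lay between 966 and 1532, with 1000, 966 and 988 without WT replicates 1, 2 and 3. The 6 libraries of the knockouts alone gave 618. No simulation was run for this comparison. The wider spread of the Cxcl10-/- group, which raised the share of unchanged genes among the simulated calls against WT, enters it as well.

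Further genes higher in Cxcr3-/- than in Cxcl10-/- were Cdca3 (3.11 ± 0.70), Xlr3a (3.04 ± 0.50) and Cdkn2c (2.94 ± 0.59). Cdca3 did not pass without Cxcr3-/- replicate 2 (adjusted p = 0.0525) or Cxcr3-/- replicate 3 (0.0506), and edgeR gave 0.149 for Cdca3 and 0.0634 for Cdkn2c. Rarres2 (-4.93 ± 0.58), Ackr1 (-4.88 ± 0.55), Ubd (-4.77 ± 0.76), Cxcl12 (-4.64 ± 0.73), Fabp4 (-4.49 ± 0.63) and the haemoglobin gene Hba-a2 (-4.48 ± 1.04) were lower in Cxcr3-/-. Hba-a2 did not pass without Cxcl10-/- replicate 2 (0.0508) or Cxcr3-/- replicate 1 (0.0839). Cxcl9 was lower by 1.44 ± 0.44 on the log2 scale without passing (adjusted p = 0.0537). Il2rg was lower in Cxcr3-/- than in Cxcl10-/- (-1.54, adjusted p = 0.00168).

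Of the 37 lists, 11 passed between the knockouts with the preset correlation, 5 higher and 6 lower in Cxcr3-/-; none passed with an estimated correlation. With its directional p fry passed 10 lists: 8 of the 11, without MHC class II (adjusted p = 0.0549), nuclear oxidative phosphorylation (0.0511) and histones (0.156), and in addition myeloid priming (0.0101) and monocytes and macrophages (0.0368), both lower in Cxcr3-/-; with its mixed p it passed 33. Mitochondrial genes had a median of 1.5 (adjusted p = 7.2e-23; 0.11 with an estimated correlation), with all 13 higher over all genes and over the list alone; mt-Atp6 was higher by 2.10 ± 0.10 and mt-Co2 by 1.30 ± 0.09. G2 and mitosis had a median of 1.65 (adjusted p = 1.25e-15; 0.114 with an estimated correlation), with 19 of 32 higher and 24 adjusted over the list alone. S phase did not pass (median 0.19, adjusted p = 0.0991), though it did without Cxcr3-/- replicate 3 (0.0126); E2f8 was higher by 2.34 ± 0.35. MHC class II had a median of 0.99 (adjusted p = 0.00733; 0.533 with an estimated correlation), with 5 of 10 higher over all genes and over the list alone, H2-Eb1 by 2.81 ± 0.51 and H2-Aa by 1.86 ± 0.37. The class II list did not pass without Cxcr3-/- replicate 2 (0.0649). Cholesterol synthesis had a median of 0.55 (adjusted p = 0.00967; 0.27 with an estimated correlation), with 5 of 24 higher over all genes and over the list alone and Idi1 higher by 2.15 ± 0.29; it did not pass without the filter on low values (0.105), and its median was 0.30 and 0.37 without Cxcl10-/- replicates 1 and 2. Histones had a median of 0.90, or 1.01 with genes at 0 counts at their bound (adjusted p = 0.0212; 0.666 with an estimated correlation), with 7 of 32 higher and 3 lower, or 8 and 3 adjusted over the list alone, and H4c4 higher by 2.20 ± 0.42. The histone list did not pass without Cxcl10-/- replicate 1 (0.238, median 0.40) or Cxcr3-/- replicate 1 (0.0971, median 0.41), and its median was 0.01 among genes above 0 in all libraries (0.72). Nor did it pass with no filter (0.159), a mean of at least 5 FPKM (0.306), quantile normalization (0.134), DESeq2 (0.0661) or the mitochondrial genes left out (0.0874).

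The lists lower in Cxcr3-/- than in Cxcl10-/- were led by the immediate-early genes, with a median of -2.43 (adjusted p = 1.75e-12; 0.11 with an estimated correlation) and 12 of 16 lower, or 13 adjusted over the list alone. Egr1 (-4.45 ± 0.49), Jun (-4.16 ± 0.38) and Ier2 (-2.39 ± 0.29) were among them. Endothelial genes had a median of -1.60 (adjusted p = 8.28e-07; 0.11 with an estimated correlation), with 6 of 12 lower, or 10 adjusted over the list alone; Stab2 (-2.58 ± 0.38), Cldn5 (-2.57 ± 0.42) and the adrenomedullin receptor partner gene Ramp2 (-2.59 ± 0.45) were among them. Stromal and bone genes had a median of -1.82 (adjusted p = 0.0364; 0.606 with an estimated correlation), with 2 of 5 lower, or 2 lower and 1 higher adjusted over the list alone. The stromal list did not pass without Cxcl10-/- replicate 1 (0.051), Cxcl10-/- replicate 2 (0.0936, median -0.54) or Cxcr3-/- replicate 2 (0.0649), or with a pseudocount of 0.1 (0.0652). Its median was -2.76 without Cxcl10-/- replicate 3. Here too Adipoq, Cxcl12 and Lepr reached the filter through the Cxcl10-/- libraries, so the direction is partly fixed by the filter. The same holds for Cdh5, Flt4, Plvap and Stab2 in the endothelial list. Nuclear oxidative phosphorylation genes had a median of -0.29 (adjusted p = 0.000465; 0.67 with an estimated correlation), with 25 of 81 lower and 5 higher, or 28 and 8 adjusted over the list alone. Ndufa8 (-1.88 ± 0.20) and Ndufs3 (-1.22 ± 0.17) were lowest in p. Its median was -0.17 without Cxcr3-/- replicate 1. That list did not pass after quantile normalization (0.717), with the mitochondrial genes left out (0.0661) or after GC and length correction (0.459).

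Ribosome biogenesis genes had a median of -0.40 in Cxcr3-/- against Cxcl10-/- (adjusted p = 0.00967; 0.18 with an estimated correlation), with 8 of 28 lower over all genes and over the list alone, the nucleolar genes Nop16 (-1.75 ± 0.26) and Nop56 (-1.15 ± 0.22) among them; the list did not pass after quantile normalization (0.084), and its median was -0.26 without Cxcl10-/- replicate 1 and -0.22 without Cxcr3-/- replicate 3. The unfolded protein response had a median of -0.60 (adjusted p = 0.0102; 0.508 with an estimated correlation), with 5 of 22 lower and 1 higher, or 8 and 1 adjusted over the list alone. Hsp90b1 (-0.70 ± 0.15) and Ppp1r15a (-1.80 ± 0.35) were among them. It did not pass without Cxcl10-/- replicate 1 (0.0636, median -0.40) or after quantile normalization (0.0771). Cytoplasmic ribosomal protein genes did not differ by this test (median -0.07, adjusted p = 0.533), though they passed without Cxcl10-/- replicate 2 (0.0341) and the median flipped to 0.19 after GC and length correction, where the list passed. In the lists of stem cell function, which did not pass, Nr4a1 (-3.77 ± 0.57) and Sult1a1, a sulfotransferase gene of the identity list (-2.08 ± 0.43), were lower and Plek, of the megakaryocyte list (2.09 ± 0.32), was higher in Cxcr3-/-.

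The mean of both knockouts against WT asks what loss of ligand and of receptor have in common. The genes with the smallest p, chosen after their values were seen, were mt-Atp6 (-1.44), mt-Cytb (-1.47) and mt-Co1 (-0.82). They fell by far more in Cxcl10-/- than in Cxcr3-/-. Rgs18 (-0.90 ± 0.13, adjusted p = 0.0146) stood at -0.95 in Cxcl10-/- and at -0.84 in Cxcr3-/-, and edgeR called it too (0.0044). limma called 42 genes (26 higher, 16 lower), with 1509 at an unadjusted p under 0.05, edgeR 19 (2 higher, 17 lower), with 15 shared in the same direction, and DESeq2 292 (115 higher, 177 lower). The split was 4 higher and 12 lower after median-of-ratios scaling, 15 and 25 after quantile normalization and 1 and 4 with the mitochondrial genes left out. The count was 6, 7 and 6 without WT replicates 1, 2 and 3, 8 without Cxcr3-/- replicate 3, 25 without Cxcl10-/- replicate 1 and 68 without Cxcr3-/- replicate 2. Of the lists, 11 passed with the preset correlation (7 higher, 4 lower) and none with an estimated one. Genes called, any difference among the 3 genotypes, numbered 1141 in limma and 912 in edgeR; without Cxcr3-/- replicates 1 and 3 the count was 702 and 717, and without WT replicates 1, 2 and 3 it was 641, 594 and 669.

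The changes of both knockouts were compared across genes, with the limit that both are measured against the same WT libraries. Pearson's r of the log2 fold changes was 0.213 and Spearman's rho 0.198, where simulated unchanged groups that share their controls gave means of 0.287 and 0.292. The same sign was found in 56.9% of genes, where the simulations gave 60.9%. The covariance was 0.0690 against a simulated 0.0475, a difference of 0.0215. At an unadjusted p under 0.05, 150 genes were higher in both knockouts and 103 lower in both, against simulated means of 39.7 and 40.1 (highest 54 for each) and 62.4 and 44.9 for independent lists. No gene passed the adjusted threshold of limma in both comparisons, as none passed in Cxcr3-/-. At an unadjusted p under 0.05, 1712 genes were higher and 1113 lower in Cxcl10-/- against WT, and 396 and 438 in Cxcr3-/- against WT. The simulated groups were all unchanged, so their counts do not give the overlap expected beside so many Cxcl10-/- changes. The WT libraries are too few to be split between the comparisons, so part or all of the overlap can come from the shared controls.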

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

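The tests on osteoblast RNA, handling on another day, a single scaling factor per library, dilution by other RNA and the splits of the samples were chosen only after the result they test was seen.

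Both knockouts were compared with the same WT libraries, and results are listed here where the direct comparison of the knockouts showed that their effects differ. In limma 1359 genes passed between Cxcr3-/- and Cxcl10-/-. The 3 libraries against 3 allow only 10 splits, too few for a share under 0.05; the real split gave 1359 genes and the highest other 1. For 11 gene lists the difference of Cxcr3-/- minus Cxcl10-/- passed camera with the preset correlation. Its median was 1.65 for G2 and mitosis, 0.99 for MHC class II presentation, 0.55 for cholesterol synthesis, 1.5 for the mitochondrial genes of oxidative phosphorylation and 0.90 for replication-dependent histones. It was -2.43 for immediate-early and dissociation stress, -1.60 for endothelial cells, -1.82 for stromal and bone cells, -0.60 for the unfolded protein response, -0.40 for ribosome biogenesis and -0.29 for nuclear genes of oxidative phosphorylation. None of the 11 passed with an estimated correlation. Single libraries moved several medians: the stromal one was -0.54 without Cxcl10-/- replicate 2 and -2.76 without Cxcl10-/- replicate 3. The histone one was 0.40 without Cxcl10-/- replicate 1 and 0.41 without Cxcr3-/- replicate 1, and the one for the unfolded protein response -0.40 without Cxcl10-/- replicate 1. Without Cxcl10-/- replicates 1 and 2 in turn the cholesterol median was 0.30 and 0.37. Ribosome biogenesis was at -0.26 without Cxcl10-/- replicate 1 and at -0.22 without Cxcr3-/- replicate 3, and the nuclear genes at -0.17 without Cxcr3-/- replicate 1. Groups of 3 libraries were not tested for outlying samples.

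Splits of the samples were counted for the other comparisons too. In Cxcl10-/- against WT the real split called 1008 genes and the highest of the other splits 0; in Cxcr3-/- against WT both values were 0. The 10 splits are too few for a share under 0.05 in both. For any difference among the 3 genotypes, 1 of 100 splits gave as many genes as the real 1141, and the highest other gave 651, so chance can be excluded at the 0.05 level. For the mean of both knockouts against WT, 3 of 100 gave at least the real 42. The highest other, with 1573, and the next, with 1348, both set the 3 Cxcl10-/- libraries against the other 6, and the rest gave at most 11. This points to a structure of the samples: the largest counts come from setting the Cxcl10-/- group apart, so this test does not exclude chance for an effect of both knockouts.

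The first pattern is the rise of endothelial and immediate-early genes, and of the stromal genes Sparc and Cxcl12, in the Cxcl10-/- libraries. The gate of these libraries (Lin-, Sca-1+, c-Kit+, CD150+, CD48-, CD135-) was meant to select LT-HSCs. How far it removed endothelial and stromal cells was not measured. Without Cxcl10-/- replicate 2 the stromal median fell from 1.94 to 0.66, and the list did not pass (camera adjusted p = 0.132). RNA from endothelial cells is a candidate source for the endothelial part. Of 30 further endothelial genes 20 passed the filter. Their median log2 fold change was 1.05, above the 95th percentile of expression-matched lists (0.38). Of the 20, 16 were positive and 10 called higher, among them Igfbp7 (3.62), Tspan7 (2.70) and Cd36 (2.66), and 1, Adgrl4 (-0.78), was called lower. A gene near 0 in WT could pass the filter by being high in Cxcl10-/-, as did Ushbp1 (0.09 FPKM in WT, 5.63 in Cxcl10-/-) and Gpr182 (0.13 and 4.42). The positive median is therefore partly fixed by the filter, and matching on the mean of all 9 libraries does not remove this. The genes named here were chosen after their values were seen. Of these 20 genes 9, and of the 12 in the list 4, reached 5 FPKM in WT, and a change in the stem cells themselves was not excluded. For Ibsp, the tables argue against osteoblasts, because Col1a1 reached at most 0.00123 of the Ibsp level in the Cxcl10-/- libraries (Col1a1 at most 0.1 and Col1a2 at most 4.9 FPKM, Ibsp at least 16.2). For the immediate-early genes, handling on another day cannot be told apart from the genotype, since 0 of the samples have a day or batch in the labels; an effect of Cxcl10 loss stays open for the whole pattern.

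The second pattern is the fall of mitochondrially encoded transcripts in the Cxcl10-/- libraries. A single scaling factor per library would move every gene of a library alike. The list's median differed by -1.55 from that of all other tested genes, which argues against such a factor. Camera had already passed the list on this difference, so the value is no separate test. The tables argue against GC content and transcript length as the whole cause, because the median moved only from -1.47 to -0.99 after correction. There 12 of the 13 genes were called, counted in either direction. Under this correction mt-Nd3 was called higher in the mean of both knockouts (0.92), so the 12 need not all be lower. Part of the change may follow GC content: 1169 nuclear genes in the GC range of the mitochondrial genes had a median of -0.41. Differences in the preparation of the cells and an effect of Cxcl10 loss stay open, and neither was tested.

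The third pattern is the fall of mitotic genes in the Cxcl10-/- libraries, which also had the most tested genes at 0. The tables argue against a general loss of weakly expressed genes: the list's median of -1.33 lay below all of 10000 lists matched on WT expression (5th percentile -0.22). For dilution by RNA of other cells, the median of the long-term HSC identity list lay 1.45 above that of the mitotic list, at 0.12, and S phase genes were at -0.19. These values argue against RNA of cells that carry neither set of genes. RNA that carries them, as endothelial RNA may for the identity list, would hold these medians up, so this test cannot exclude it. After GC and length correction the mitotic median was -1.41. A smaller share of cells in G2 and mitosis among the Cxcl10-/- LT-HSCs is a candidate explanation that these data could not separate from a difference in preparation. The S phase list, at -0.19, did not pass and so lends no such support to a smaller share of cycling cells as a whole. The list of replication-dependent histones, at -0.71, passed camera with the preset correlation (adjusted p = 0.000292) but not with an estimated one (0.427). These lists therefore leave a smaller share of cycling cells as a whole undecided.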

How the results depend on the processing

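The tests with edgeR, DESeq2, GC and length correction, the mitochondrial genes left out, genes above 0 in all libraries and the marker lists left out were chosen only after the result was seen; the others were planned.

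For Cxcl10-/- against WT (1008 genes), the count was 591 with no filter on low values, 616 without the intensity trend, 609 after GC and length correction and 648 with a 2-fold minimum, which can only lower it. Leaving out single libraries gave 282 to 1192. The other alternatives stayed within 1.5 times, among them edgeR with 785, the 6 samples with 712 and DESeq2 with 1498. Of the 1008 genes, 625 were also called in the same direction by edgeR, 544 with no filter and 469 after GC and length correction.

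For Cxcr3-/- against WT (0 genes), array weights gave 4, DESeq2 78 and DESeq2 without independent filtering 30; single libraries left out gave 0 to 1. Every other alternative gave 0.

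For Cxcr3-/- against Cxcl10-/- (1359), the count was 818 with no filter, 688 with array weights and 618 with only the 6 samples, where fewer samples estimate the spread. Single libraries left out gave 596 to 1532. Of the 1359 genes, 936 were also called by edgeR and 824 after GC and length correction.

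The mean of both knockouts against WT (42) was the least stable. It gave 18 genes with a pseudocount of 0.1 and of 0.5, 3 with no filter (mt-Cytb, Spag6l and Abcf1), 16 with median-of-ratios scaling, 0 without the intensity trend, 251 with array weights, 25 with a replicate block, 19 with edgeR and 292 with DESeq2. It gave 5 with the mitochondrial genes left out (Rgs18, Sdcbp, Abcf1, B2m and Msmo1) and 4 after GC and length correction (mt-Cytb, mt-Atp6, mt-Co1 and mt-Nd3); these names were chosen after the values were seen. Single libraries left out gave 6 to 68. For any difference among the 3 genotypes (1141), the count was 571 with no filter, 530 without the trend and 660 with array weights, and 594 to 1132 with single libraries left out. Where no construction is named, the cause was not tested.

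The number of lists past the threshold fell to 0 in all 3 comparisons of a pair of genotypes with an estimated correlation, which widens the test by the correlation of the members. In Cxcr3-/- against WT it fell from 5 to 3 without the intensity trend and to 0 with the directional p of fry, and ranged from 3 to 8 with single libraries left out (12 to 14 for Cxcl10-/- against WT and 8 to 12 between the knockouts). In Cxcr3-/- against WT the mitochondrial list reversed to 0.17 after GC and length correction, without passing there. Cytoplasmic ribosomal proteins reversed to 0.19 between the knockouts under the same correction. The cause was not tested beyond the trend that the correction removes.

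Of the 75 named genes called in Cxcl10-/- against WT, all 75 kept their direction under all alternatives run on them and 44 kept their call; between the knockouts it was 66 of 66 and 42. No named gene reversed. The correlation between the changes of both knockouts stayed between 0.173 and 0.288 with single libraries left out.

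A replicate block called 810 genes in Cxcl10-/- against WT. The residuals of libraries with the same number correlated at -0.09 to 0.03 (9 pairs) and of others at -0.05 to 0.1 (18 pairs), so the numbers do not pair the libraries. Depth limits weakly expressed genes: Cxcr3 had at most 8 counts in a library, so its loss was not detectable at this depth.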

Other observations

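The values here were chosen only after the result was seen, and no hypothesis is attached to them.

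Transcripts of the sort markers varied between the libraries. Kit (c-Kit) stood at 98.1, 110 and 106 FPKM in the WT libraries, at 81.4, 72.3 and 45.8 in Cxcl10-/- and at 127, 109 and 110 in Cxcr3-/-. Ly6a (Sca-1) stood at 271, 338 and 329 in WT, at 320, 379 and 307 in Cxcl10-/- and at 194, 270 and 293 in Cxcr3-/-. Flt3 (CD135), which the gate excludes, stood at 4.17, 6.08 and 4.75 in WT, at 13.8, 9.7 and 6.45 in Cxcl10-/- and at 6, 6.91 and 8.61 in Cxcr3-/-. Cd48, which the gate excludes as well, stood at 17.8, 20.1 and 8.76 in WT, at 0, 7.94 and 0 in Cxcl10-/- and at 7.24, 19.6 and 0.18 in Cxcr3-/-. None of these 4 genes passed in limma in either knockout against WT; edgeR gave an adjusted p of 0.026 for Kit in Cxcl10-/- against WT.

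Il2rg, which lies near Cxcr3, stood at 57.2, 105 and 93.8 FPKM in Cxcr3-/-, at 194, 170 and 154 in WT and at 270, 217 and 244 in Cxcl10-/-. Its adjusted p in Cxcr3-/- against WT was 0.441 in limma. The list of Cxcr3 neighbours had a median of 0.15 there, and none of its 13 tested genes passed.

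Hba-a2 stood at 1.17, 23.2 and 19.9 FPKM in WT, at 18.3, 243 and 150 in Cxcl10-/- and at 0.5, 4.31 and 7.05 in Cxcr3-/-. The Y-linked genes Ddx3y and Eif2s3y were expressed in all 9 libraries, Ddx3y at 23.5 FPKM or more and Eif2s3y at 36.7 or more.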
